A study of Equus caballus with 24 samples.

How the data were processed

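Gene expression in whole blood was measured in 24 horses with one-colour Agilent horse expression arrays, 1 horse per array and 1 array per horse. Per the labels' protocols, total RNA was extracted with a kit for stabilised blood, spiked with control transcripts, amplified and labelled with the dye Cy3. Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.1.1.1. The horses belonged to 3 athletic disciplines (thoroughbred racehorses, standardbred trotters and endurance horses), with 8 horses in each. Within a discipline 4 horses were healthy and 4 had inflammatory airway disease, a mild inflammation of the lower airways, which gave 6 groups of 4. Groups were taken from the labels. Replicate numbers were given in accession order. The healthy and the inflamed horse of the same discipline and number also have consecutive running numbers in their sample names. Discipline goes together with breed, age range and training, which cannot be told apart here, and the labels used here do not give the sex of a horse.

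The deposited values are log2 signals of 43803 features on 24 arrays, with 0 missing values, and how background was subtracted or spots were summarised is not given in the sources used here. The base of the logarithm was taken from the values, whose highest point on an array lay between 18.0 and 18.4, as an extended scanner range gives on the log2 scale. The deposited log2 values were not scaled between arrays, since their 75th percentile ran from 8.56 to 10.13. Each array's own 75th percentile was therefore subtracted, so that a level of 0 is the 75th percentile of that array. The 25% of features with the lowest mean over all 24 arrays were left out, which left 32852 features for testing. The file carries no flag for spots above background, so a level near the bottom of an array is a signal and not a call of absence. No 2 arrays held identical values, and the table had 0 columns of other samples.

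The files do not pair the feature numbers with gene names, and no table of the array's annotation was used here. Each feature was therefore tested on its own, where the plan had been to test 1 feature per named gene. The planned gene lists, cell type markers, covariates for sex and for the balance of neutrophils and T cells, and the mean of the features of a gene could not be run. Features are given by number. Of the planned rule for named genes, the part that needs no name was kept: for each comparison over all horses or between disciplines, the features past the threshold with the largest rise and fall are given, at most 2 in each direction, or, where none passed, the 2 of lowest unadjusted p in each direction, said not to pass.

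Tests were run with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups in 1 fit, the empirical Bayes variance and a Benjamini-Hochberg adjusted p under 0.05. Airway inflammation was tested as the mean of the 3 differences within disciplines and within each discipline. Disciplines were tested as the mean of their differences among healthy and among inflamed horses. A moderated F test asked whether the difference with inflammation itself differed between disciplines. Correlations across features between disciplines were tested two-sided over all 4900 relabelings of state within both disciplines, and the 75th percentiles of the arrays with two-sided exact permutation tests. Features that split the horses by a wide gap in signal were tested with Fisher's exact test in Python 3.11.15 with SciPy 1.17.1 and NumPy 2.4.6. Plots were drawn with Matplotlib 3.10.9.

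The sample names carry running numbers, from 7002 to 7025, and no slide is named in the labels. After the data were examined, arrays were found to deviate from their group means together in sets of 4 consecutive numbers, though not equally in each. There are 6 such sets, each holding 1 healthy and 1 inflamed horse of 2 disciplines. The mean correlation of deviations within sets was 0.266 (36 pairs of arrays, correlation across features). It was 0.349 for the healthy and inflamed horse of consecutive numbers, 0.224 between the 2 disciplines of a set, and 0.073 between neighbouring numbers that lie in different sets. The means of the single sets, in order of number, were 0.348, 0.571, 0.033, 0.070, 0.194 and 0.377. Those of 0.033 and 0.070 (numbers 7010 to 7013 and 7014 to 7017) were no higher than between neighbouring numbers of different sets. Reassigning horses to sets within their groups 100000 times gave a one-sided permutation p of 6e-05. With the 75th percentile as a covariate the mean correlation within sets was 0.058. The sets were therefore also fitted as a fixed block, which left 13 residual degrees of freedom in place of 18, and as a random block, with a correlation of 0.272. Each pair of disciplines was also compared within the 2 sets that hold both.

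The number of arrays limits the precision. The median standard error of a log2 difference was 0.18 for inflammation over all disciplines, 0.32 within 1 discipline and 0.23 between disciplines. The procedure was tested on simulated data with the real features' means and spread, in which 200 of 32852 features were changed. For inflammation over all disciplines, 67.5% of changes of 1 on the log2 scale and 91.0% of changes of 2 were called. Within disciplines these shares were 20.5% and 69.0% for thoroughbred, 24.0% and 67.5% for standardbred and 15.0% and 74.0% for endurance horses. Between disciplines they were 49.0% and 85.5% for standardbred against thoroughbred, 50.5% and 83.0% for endurance against thoroughbred, and 51.5% and 84.5% for endurance against standardbred. The simulation had no array sets in it.

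The alternatives chosen before the data were examined were quantile normalization, scaling by the array median, no filter on dim features, leaving out the 50% of features with the lowest mean, array weights, a variance prior with trend and robust estimation, fits on only the arrays compared, models with state and discipline added or with state alone, the running number as a covariate, healthy horses only, an adjusted p under 0.10 and leaving out each horse in turn. The array sets as blocks, pairs of consecutive running numbers as a random block, the 75th percentile as a covariate, and leaving out 2 arrays with a raised floor were added after the data were examined. So were the dealing out of array deviations in whole running-number pairs or whole sets, 100 times each, to give the sharing of calls between unchanged groups, the count of features without overlap in divisions that keep pairs together, and the test of the 75th percentiles over whole pairs.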

Results

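Signals of 43803 features were measured in the blood of 24 horse athletes, 4 healthy and 4 with inflammatory airway disease in each of 3 disciplines. Thoroughbreds were 2 to 5 years old, standardbred trotters 2 to 8 years and endurance horses 7 to 12 years. The 75th percentile of the log2 signal averaged 9.71 ± 0.31 (SD, n = 8) in thoroughbreds, 9.23 ± 0.33 (SD, n = 8) in standardbreds and 9.39 ± 0.38 (SD, n = 8) in endurance horses. Before scaling, the standardbred arrays were dimmer than the thoroughbred arrays by 0.48 on the log2 scale (difference -0.48, two-sided exact permutation p = 0.00777, 0.0233 after adjustment for 3 comparisons) if horses are taken as independent. Over divisions of whole running-number pairs the difference did not pass (4 of 70 divisions as large, two-sided exact permutation p = 0.0571, adjusted 0.171). The other 2 differences did not pass, with adjusted exact permutation p of 0.138 for endurance against thoroughbred and 0.377 for endurance against standardbred. The arrays of endurance inflamed replicates 1 and 3 stood apart: 12.1% and 2.46% of their values lay under a log2 signal of 2, against 26.1% to 32.5% on the other 22 arrays.

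**Figure D1:**
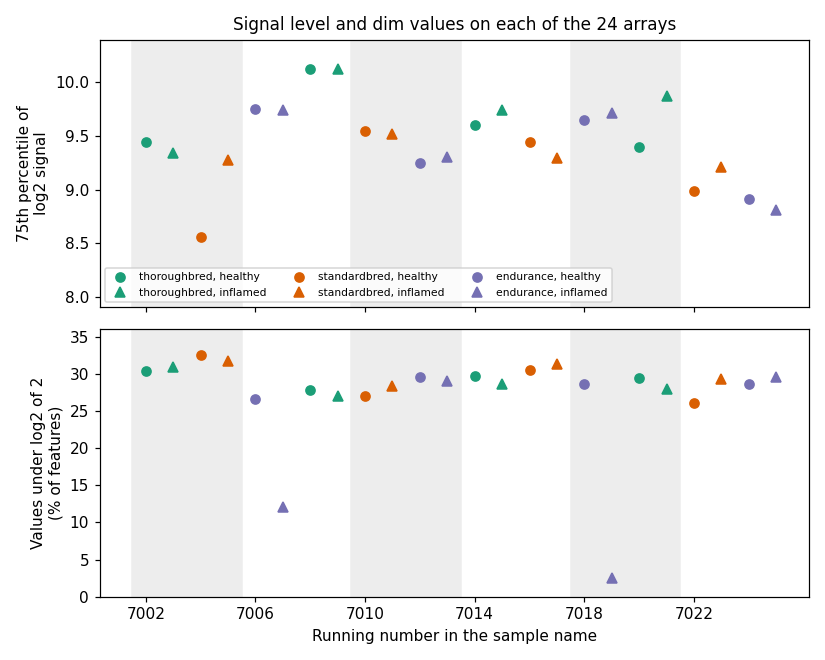
The upper panel shows the 75th percentile of the log2 signal and the lower panel the percentage of features with a log2 signal under 2, for each of the 24 arrays by the running number in the sample name. Colours are disciplines, circles are healthy and triangles inflamed horses, and shading marks alternate sets of 4 consecutive numbers; the lower panel has 2 endurance inflamed arrays at 12.1% and 2.46%, under the other 22 at 26.1% to 32.5%.

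The first question was whether airway inflammation goes with a change in blood gene expression over all disciplines. None of the 32852 features passed. Feature 18801 was 1.59 ± 0.40 (SE) higher on the log2 scale in the 12 inflamed than the 12 healthy horses, with levels of -6.19 ± 1.24 and -7.79 ± 1.03 (SD, n = 12 each) relative to the 75th percentile of the array. Feature 36669 was 0.57 ± 0.15 (SE) higher, at -4.39 ± 0.34 against -4.96 ± 0.49 (SD, n = 12 each). Feature 32698 differed by -0.98 ± 0.22 (SE), at -2.91 ± 1.00 in inflamed and -1.93 ± 0.67 in healthy horses (SD, n = 12 each). Feature 23077 differed by -1.13 ± 0.28 (SE), at -5.02 ± 0.62 and -3.89 ± 0.75 (SD, n = 12 each). These 4 features had the lowest unadjusted p in each direction, and each had an adjusted p of 1.00 in limma. Feature 18801 was dim, with a deposited log2 signal under 2 in 7 healthy and 3 inflamed horses, and its difference was 0.89 with array weights. That of feature 36669 was 0.36 with quantile normalization. Feature 36669 was higher in the inflamed horses of all 6 array sets, by 0.31 to 0.84, and feature 23077 was lower in all 6, by differences of -2.19 to -0.05. Feature 18801 was higher in 5 of the 6 sets (-0.09 to 2.44) and feature 32698 lower in 5 of the 6 (-1.43 to 0.10). The sets hold the same arrays on which the 4 features were picked, so this agreement follows in part from the picking.

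At an unadjusted p under 0.05, 842 features were counted, fewer than the 1643 that chance gives on average among 32852 independent features. With the array sets as a fixed block 0 features passed as well, and 1522 had an unadjusted p under 0.05. The 95% interval of the difference lay within a 2-fold change in either direction for 82.0% of all tested features and for 93.2% of the brighter 50% of the array.

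Within disciplines, where 4 inflamed were compared with 4 healthy horses, limma called 0 features in thoroughbred, 0 in standardbred and 0 in endurance horses. No feature is named for these comparisons because none passed the test. Features with an unadjusted p under 0.05 numbered 383 in thoroughbreds, 598 in standardbreds and 3043 in endurance horses, and the lowest adjusted p were 1.00, 1.00 and 0.167. Over all other settings and runs without 1 horse they numbered 246 to 3950, 356 to 1936 and 494 to 10358. Without standardbred healthy replicate 3 there were 1405 in standardbreds, and without endurance inflamed replicate 3 there were 1459 in endurance horses. With no filter on dim features there were 10358 in endurance horses, with the dimmer 50% left out 494, and with array weights 3950 in thoroughbreds and 1936 in standardbreds. Of the 3043 features in endurance horses, 2848 had higher and 195 lower values in inflamed horses, and 2571 of the 2848 belonged to the dimmer 10951 of the tested features. Without the 2 endurance arrays with a raised floor, 1477 features had an unadjusted p under 0.05 and 0 passed. Without endurance inflamed replicate 2, which leaves those arrays 2 of 3 in their group, 523 features passed, 520 of them higher. With quantile normalization 6 features passed in endurance horses, all lower in inflamed horses, and with array weights 2 passed in endurance and 1 in standardbred horses, all higher. With pairs of consecutive running numbers as a random block 23 passed in endurance horses, all higher (lowest adjusted p = 0.0404). The 95% intervals lay within a 2-fold change for 58.7% of features in thoroughbreds, 57.0% in standardbreds and 55.3% in endurance horses.

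The design also asks whether the response to airway inflammation differed between disciplines. No feature passed the test of discipline by state, where the lowest adjusted p was 0.889 and 1653 features had an unadjusted p under 0.05 (265 to 5075 over other settings and runs without 1 horse). There were 917 without endurance inflamed replicate 3, 1050 without endurance healthy replicate 1 and 2656 without endurance inflamed replicate 2. With quantile normalization and with array weights 1 feature passed each. Across features, the differences with inflammation in thoroughbreds and standardbreds had a Pearson r of 0.118 and a Spearman rho of 0.192 (exact relabeling p of r = 0.523). For thoroughbreds and endurance horses r was -0.011 and rho 0.023 (exact relabeling p = 0.962), and for standardbreds and endurance horses r was -0.244 and rho -0.276 (exact relabeling p = 0.220). After adjustment over the 3 pairs the p were 0.785, 0.962 and 0.659. Features are not independent replicates, and for unrelated labels |r| reached 0.428, 0.551 and 0.401 in 5% of relabelings. The relabelings did not keep the running-number pairs, within which the real labels are balanced. Some therefore carry differences between array sets that the real labels do not, which can widen the spread of r and raise these p.

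Standardbreds were next compared with thoroughbreds. Feature 39486 was 4.87 ± 0.55 (SE) higher on the log2 scale in standardbreds (3.80 ± 0.88 against -1.07 ± 1.36, SD, n = 8 each; adjusted p = 0.000177), and all 8 standardbreds lay above all 8 thoroughbreds. Feature 21533 was 3.22 ± 0.56 (SE) higher (-4.99 ± 0.98 against -8.21 ± 0.97, SD, n = 8 each; adjusted p = 0.00769), again without overlap between the 8 horses of each discipline. The deposited log2 signal of feature 21533 was under 2 in 5 of the 8 thoroughbreds, so the size of its difference depends on where the floor of the array is. Feature 37344 was lower in standardbreds by a difference of -5.37 ± 1.20 (SE), at -3.51 ± 2.73 against 1.86 ± 2.47 (SD, n = 8 each; adjusted p = 0.0203). Its horses were either high or low, with 6 thoroughbreds, 1 standardbred and 1 endurance horse high. Feature 41533 was lower by a difference of -4.48 ± 0.83 (SE), at -7.26 ± 2.02 against -2.78 ± 1.25 (SD, n = 8 each; adjusted p = 0.0107), and its signal was under 2 in 6 of the 8 standardbreds, so the same holds for it. Over the other settings and the runs without 1 horse, feature 39486 passed in 39 of 40, feature 21533 in 38 of 39, feature 37344 in 35 of 40 and feature 41533 in 37 of 39.

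Among all features, 2479 passed, of which 2111 were higher and 368 lower in standardbreds, and 593 differed by more than 2-fold. The 2 disciplines did not overlap for 511 higher and 30 lower features, where chance gives 5.11 in all (0.0155% of features) if the 16 horses are independent. When running-number pairs were kept together, 2 of 35 divisions, the real one included, gave at least the 541 features of both directions, and the highest other count was 638. With the array sets as a fixed block 75 features passed, 63 higher and 12 lower, and 68 of the 75 were also among the 2479. The 2479 features all kept their direction, with a median size of 0.55 against 0.72 without the block (median SE 0.18 and 0.19), on the same arrays that gave the calls. In that fit features 39486, 21533 and 41533 passed (adjusted p of 0.0106, 0.00104 and 0.0312) and feature 37344 did not (difference -5.81, adjusted p = 0.0841). Within the 2 sets that hold both disciplines, the differences were 5.26 and 5.84 for feature 39486, 3.60 and 4.63 for feature 21533, -8.04 and -7.15 for feature 37344, and -6.39 and -4.00 for feature 41533. In these 2 sets the features called higher had median differences of 0.77 and 0.52 and those called lower -1.21 and -0.76, on arrays that also took part in the calls. The count was 29 with the 75th percentile as a covariate and 0 among healthy horses only, where 3886 features had an unadjusted p under 0.05. Scaling by the array median gave 153 features, 108 higher and 45 lower, a share of 70.6% higher against 85.2% with the 75th percentile, and quantile normalization gave 1072.

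The largest rises and falls called between endurance horses and thoroughbreds were in features that were high in some horses and low in the others. Feature 16600 was 11.86 ± 1.83 (SE) higher in endurance horses (2.70 ± 4.92 against -9.16 ± 0.34, SD, n = 8 each; adjusted p = 0.00161). Feature 32883 was 11.32 ± 1.87 (SE) higher (3.50 ± 4.86 against -7.82 ± 0.71, SD, n = 8 each; adjusted p = 0.00288). Both were high in 7 of the 8 endurance horses and in none of the thoroughbreds. The deposited log2 signal of feature 16600 was under 2 in all 8 thoroughbreds, so its difference depends on where the floor of the array is, and that of feature 32883 was under 2 in 3 of them. Feature 25958 was lower by a difference of -5.05 ± 1.60 (SE), at -3.14 ± 4.85 against 1.91 ± 1.51 (SD, n = 8 each; adjusted p = 0.0415). Feature 6842 was lower by -4.82 ± 1.45 (SE), at -2.30 ± 4.54 against 2.52 ± 1.05 (SD, n = 8 each; adjusted p = 0.0348). Features 25958 and 6842 were low in 4 of the 8 endurance horses, in 1 standardbred and in none of the thoroughbreds. Their deposited log2 signal was under 2 in 2 of the 8 endurance horses for feature 25958 and in 1 for feature 6842. The size of these differences therefore also depends on where the floor of the array is. Over the other settings and the runs without 1 horse, features 16600 and 32883 passed in 38 of 39 and 39 of 40, while feature 25958 passed in 21 of 40 and feature 6842 in 24 of 40. Of the 24 runs without 1 horse alone, feature 25958 passed in 13 and feature 6842 in 15.

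**Figure D2:**
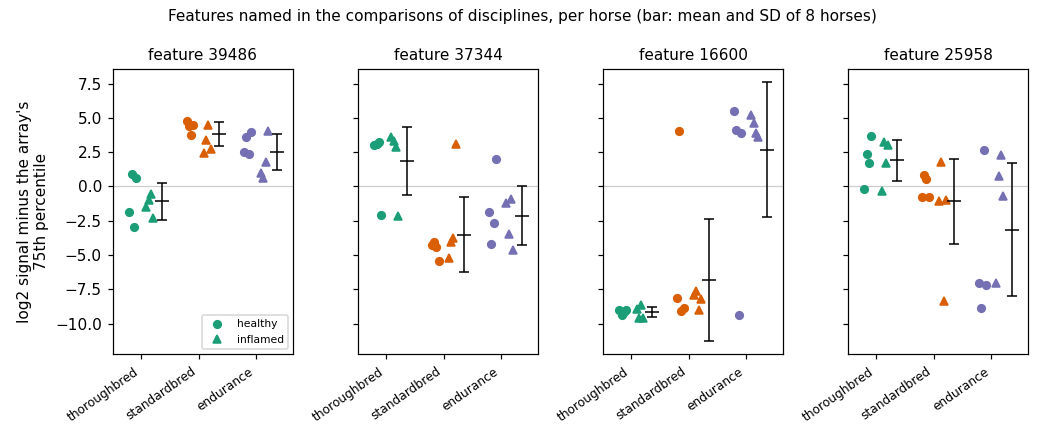
The 4 panels show the log2 signal minus the 75th percentile of the array for features 39486, 37344, 16600 and 25958 in each of the 24 horses, by discipline. Circles are healthy and triangles inflamed horses, the bars are the mean and SD of the 8 horses of a discipline, and the line marks a level of 0; feature 39486 separates all 8 standardbreds from all 8 thoroughbreds, and feature 16600 is high in 7 of 8 endurance horses and in 1 standardbred.

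In all, 4464 features passed, 3778 higher and 686 lower in endurance horses, with more than a 2-fold difference for 2069. Non-overlapping values were found for 201 higher and 27 lower features, where chance gives 5.11 if horses are independent. With pairs kept together 2 of 35 divisions gave at least the 228 of both directions (highest other 2857). With the array sets as a fixed block 2551 features passed, 2292 higher and 259 lower, and 2183 of them were also among the 4464, whose median size was 0.84 against 0.95 without the block. In that fit features 16600, 32883, 25958 and 6842 passed (adjusted p of 0.0117, 0.0158, 0.0402 and 0.0386). Within the 2 sets that hold both disciplines, the differences were 14.89 and 6.57 for feature 16600, 13.42 and 6.48 for feature 32883, -9.90 and -0.88 for feature 25958, and -8.97 and -0.93 for feature 6842. In these sets the features called higher had median differences of 0.90 and 0.96 and those called lower -0.57 and -0.23, on arrays that also took part in the calls. The direction of the whole depended on the scaling. Quantile normalization gave 848 higher and 993 lower features (46.1% higher against 84.6%) and array median scaling 952 higher and 1092 lower. The median difference of all tested features was 0.15 with the 75th percentile, -0.11 with the array median and -0.05 with quantile normalization. Without the 2 arrays with a raised floor 3317 features passed with the 75th percentile, 2737 of them higher. The other scalings were not run without these arrays. Among healthy horses only, 0 features passed, with 2341 at an unadjusted p under 0.05.

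Both comparisons share the thoroughbred arrays. Of the features higher than in thoroughbreds, 1135 were called in both standardbred and endurance horses, and 102 of those lower. Independent lists of these sizes would share 243 and 7.68, but lists that share the thoroughbred arrays are not independent. Unchanged groups simulated against the same thoroughbreds shared 0. Few features can be called between unchanged groups, so this 0 does not show how far the shared arrays raise the sharing. The differences of the 2 comparisons correlated with r = 0.626 across features against 0.501 in the simulation, and their covariance was 0.25 against 0.07. The thoroughbreds were also divided once by replicate number, with a separate part for each comparison. Then r was 0.607, and 0.406 with the 2 parts exchanged. Other divisions of the thoroughbreds were not run. These values take the horses as independent. When the deviations of the arrays from their group means were dealt out again in whole running-number pairs, as unchanged groups, 3 of 100 draws shared at least 1135 higher features (highest 2442) and 3 of 100 at least 102 lower ones (highest 1696), while r was at least 0.626 in 38 of 100 and the covariance at least 0.25 in 7 of 100. With the array sets as a fixed block 53 higher and 10 lower features were shared, r was 0.745 and the covariance 0.21. When deviations were dealt out in whole sets and fitted with the same block, the median of 100 draws was 0 shared features in each direction (highest 1931 and 14), an r of 0.519 and a covariance of 0.06. At least as many higher features were shared in 1 draw and lower ones in 1, r was as large in 5 and the covariance in 0.

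Endurance horses and standardbreds had 42 calls, fewer than the other pairs of disciplines, but with the 75th percentile as a covariate they had 31 against 29 for standardbreds and thoroughbreds. Feature 16600 was 9.55 ± 1.83 (SE) higher in endurance horses (2.70 ± 4.92 against -6.85 ± 4.45, SD, n = 8 each; adjusted p = 0.0418), and feature 25399 was 9.52 ± 1.86 (SE) higher (3.73 ± 4.87 against -5.80 ± 4.54, SD, n = 8 each; adjusted p = 0.0451). Both were high in 7 endurance horses and 1 standardbred. The deposited log2 signal was under 2 in 7 of the 8 standardbreds for feature 16600 and in 4 of the 8 for feature 25399, so the size of these differences depends on where the floor of the array is. Feature 32698, which had also differed with inflammation without passing, was lower in endurance horses by a difference of -1.59 ± 0.27 (SE), at -3.16 ± 0.79 against -1.58 ± 0.64 (SD, n = 8 each; adjusted p = 0.0298). Feature 43621 was lower by -1.51 ± 0.27 (SE), at -3.65 ± 0.66 against -2.14 ± 0.59 (SD, n = 8 each; adjusted p = 0.0413). Features 32698 and 43621 moved alike over most horses, so their falls may not be separate results. Both were highest in standardbred healthy replicate 1 (-0.80 and -1.34) and lowest in endurance inflamed replicate 2 (-4.75 and -5.17). Most of these calls were easily lost: over the other settings and the runs without 1 horse, feature 16600 passed in 13 of 39, feature 25399 in 13 of 40, feature 32698 in 25 of 40 and feature 43621 in 19 of 40. With array weights the differences were 5.36 for feature 16600 and 5.26 for feature 25399. In all 42 features passed, 13 higher and 29 lower. With the array sets as a fixed block 6 passed and none of these 4 features did (differences of 9.61, 9.92, -1.48 and -1.37, adjusted p of 0.157, 0.110, 0.156 and 0.208). Within the 2 sets that hold both disciplines, the differences were 6.17 and 12.30 for feature 16600, 6.0 and 12.73 for feature 25399, -2.13 and -0.71 for feature 32698, and -2.06 and -0.74 for feature 43621. These arrays also took part in the calls. Without the 2 arrays with a raised floor 2 features passed, and among healthy horses only 0 did, with 1856 at an unadjusted p under 0.05. With quantile normalization 171 features passed, 9.36% of them higher, and with array median scaling 130, 10.0% of them higher, against 30.95% with the 75th percentile. The median difference of all tested features was 0.02 with the 75th percentile, -0.25 with the array median and -0.10 with quantile normalization.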

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

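In this part, the tests on quantile normalization, on the 75th percentile as a covariate and on the array sets as a block were chosen after the results were seen. For the 75th percentile, the requirement that at least 50% of the calls remain was added after its values were known, and it left the standardbred test undecided where size alone had argued against brightness. The split of picked features by direction was also added after the results were seen. The tests on the raised floor and on picked features were added after the data were examined, but before their own values were seen, as were the divisions that keep running-number pairs together. For 16 measures in the 6 groups of 4 horses, 96 sets of 4 values in all, 11 values stood far from the other 3 of their group, where chance gives about 4.80 for independent measures. These were not independent: all 11 are of named features, which were picked for their differences, and several of these features divide the horses alike, so the 2 counts cannot be set against each other. Thoroughbred healthy replicate 4 had a level of -2.11 for feature 37344 and thoroughbred inflamed replicate 4 a level of -2.15, against 3.01 to 3.23 and 2.90 to 3.58 in the others of their groups. Standardbred healthy replicate 2 had levels of 4.08 for feature 16600 and 5.15 for feature 25399, against -9.06 to -8.12 and -9.04 to -6.80. Endurance healthy replicate 3 was the opposite for the same features, with -9.35 for feature 16600, -8.27 for feature 25399 and -8.48 for feature 32883, where the other 3 horses lay at 3.88 or higher. The same horse had 2.64 for feature 25958 and 2.93 for feature 6842, against -8.88 to -7.08 and -7.67 to -6.12. Standardbred inflamed replicate 3 had -3.60 for feature 21533, against -5.68 to -5.59, and endurance healthy replicate 4 had -6.75 for feature 41533, against -4.12 to -3.70.

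In inflamed endurance horses 2848 features had nominally higher values, most of them dim. Airway inflammation as the source was examined on 12085 features of the dimmer 50% of the array, picked by another rule than the 2848. These were higher on both raised-floor arrays than in every healthy endurance horse, and some of them were among the features left out of testing. On those 2 arrays they were higher by a median of 2.73 on the log2 scale and on inflamed replicates 2 and 4 by 0.20, which is 7.31% of that size. Picking on the 2 arrays enlarges the difference there, so this share cannot decide on airway inflammation by itself. On replicates 2 and 4, 77.6% of the picked features were above the mean of the healthy horses. A rise with inflammation therefore stays open, though the picking favours low healthy values. Without the 2 arrays 1477 features had an unadjusted p under 0.05, under the 1643 that chance gives for independent features, while the median standard error rose from 0.32 to 0.38. The 1477 were still more than the 383 in thoroughbreds and 598 in standardbreds. The lowest adjusted p in limma was 0.0770 without the 2 arrays and 0.167 with them. A raised floor on 2 arrays is a candidate explanation for these features, but the count without them does not show that it explains all of them. Of the 35 ways to divide the 8 endurance horses, 9 gave at least the 3043 features of the real one, and the highest other count was 11379, so chance was not excluded. Some of these ways put whole running-number pairs on the same side, which the real one does not, so their share cannot decide on chance.

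More features were called higher than lower than in thoroughbreds in both other disciplines. For endurance horses 1 scaling factor per array is a candidate explanation, since the share of higher features was 46.1% with quantile normalization. For standardbreds that share was 78.9%, which argues against it there. The endurance share cannot be told apart from the 2 raised-floor arrays, since quantile normalization was not run without them. With the 75th percentile and without these arrays, 2737 of the 3317 called features (82.5%) were higher. Array sets were tested on the 1000 features of lowest unadjusted p between the disciplines, picked on arrays of sets with only 1 of the 2 disciplines. Picking by low p enlarges the differences on those arrays, so a part is lost on other arrays even without set effects. The share kept therefore cannot decide on set effects by itself. Within the sets that hold both, standardbreds kept 10.3% of the median difference (0.26 of 2.49, 70.6% in the same direction) and endurance horses 35.6% (0.49 of 1.37, 89.1% in the same direction), with 15.8% kept by the 324 that were higher and 8.18% by the 676 that were lower in standardbreds, and 55.4% by the 627 higher and 16.6% by the 373 lower in endurance horses. With the sets as a fixed block, the called features had a median size of 0.55 against 0.72 for standardbreds (median SE 0.18 and 0.19) and 0.84 against 0.95 for endurance horses (median SE 0.24 and 0.25), all in the same direction, over features chosen without the block. Set effects stay open as a part of the standardbred calls and of the endurance calls, most of all the lower ones. In the 2 sets that hold both endurance horses and thoroughbreds, the 627 higher picked features had medians of 0.76 and 0.74 in the picked direction. The 373 lower ones had 0.55 and -0.08, a reversal in the second set. With the 75th percentile as a covariate, the median size of the called features was 61.04% of its value for standardbreds (0.44 against 0.72, median SE 0.17 and 0.19) and 83.9% for endurance horses (0.80 against 0.95, median SE 0.24 and 0.25), over features chosen for their size without it. For endurance horses 3002 features still passed, which argues against brightness as the whole source. For standardbreds 29 passed, as the differences were smaller, and as brightness may differ between these disciplines (exact permutation p = 0.00777 over horses, 0.0571 over running-number pairs), the 2 cannot be told apart there. Breed, age and training, which the design ties to discipline, stay open and were not tested apart.

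Other divisions of the horses bear on the same counts. Of 100 divisions of the 16 horses within state, the real one included, 1 gave at least the real count for standardbred against thoroughbred (2479, highest other 0), 1 for endurance against thoroughbred (4464, highest other 2222) and 2 for endurance against standardbred (42, highest other 359). Such counts were rare if horses are independent, though for endurance against standardbred another division far exceeded the real one. Arrays with neighbouring numbers were not independent. When the healthy and inflamed horse of consecutive numbers were kept together, 3 of 35 divisions gave as many for standardbred against thoroughbred (highest other 4461), 3 of 35 for endurance against thoroughbred (highest other 7894) and 5 of 35 for endurance against standardbred (highest other 6316), so chance was not excluded. The division with 7894 features put the 2 array sets that hold both disciplines on one side and the other arrays on the other, and that with 4461 also followed whole sets, while that with 6316 cut 1 set. Counts above the real ones point to a structure of the arrays. The counts with the sets as a fixed block were 75, 2551 and 6, and the calls made without it kept their direction in each comparison. Those calls were picked for their differences on the same arrays, so the kept direction says little about set effects. For inflammation, 26 of 35 divisions gave at least the 383 features at an unadjusted p under 0.05 in thoroughbreds (highest other 7509), 30 of 35 the 598 in standardbreds (highest other 2636) and 58 of 100 the 842 over all disciplines (highest other 9230). For discipline by state 28 of 100 gave at least 1653 (highest other 9127). The real labels put 1 healthy and 1 inflamed horse in each running-number pair, while these divisions could put whole pairs on the same side. Such divisions carry differences between array sets that the real one does not. Divisions that swap state only within pairs were not run, so these 4 shares cannot decide on chance. Within each discipline, the division with the highest other count kept all 4 running-number pairs together and so followed the array sets, and in endurance horses it also put both raised-floor arrays on the same side. The make-up of the highest divisions over all disciplines was not examined.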

How the results depend on the processing

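The settings with blocks, with the 75th percentile as a covariate and without the raised-floor arrays were chosen after the data were examined. The cause was not tested unless given. Inflammation over all disciplines gave 0 features in each of the 15 other settings and in each of the 24 runs without 1 horse (510 to 2076 at an unadjusted p under 0.05). Inflammation in thoroughbreds gave 0 in 14 settings and 24 runs. Standardbreds gave 0 in 13 of 14 settings and all 24 runs and 1 with array weights. Endurance horses gave 6 with quantile normalization, 2 with array weights, 23 with pairs of running numbers as a random block and 0 in the other 11. Leaving out 1 horse gave 0 to 523 there: 523 without endurance inflamed replicate 2, 30 without endurance inflamed replicate 4 and 1 without thoroughbred healthy replicate 4. Discipline by state gave 1 with quantile normalization, 1 with array weights and 0 in the other 11 settings and all 24 runs.

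The count for standardbred against thoroughbred, 2479 as reported, was 1072 with quantile normalization, 153 with array median scaling, 1003 with no filter on dim features, 14896 with array weights, 5237 with only the arrays compared, 0 with healthy horses only (fewer samples), 7667 at an adjusted p under 0.10, 75 and 1206 with the array sets as a fixed and a random block, 74 with running-number pairs as a random block, 29 with the 75th percentile as a covariate and 3760 without both raised-floor arrays. For endurance against thoroughbred, 4464 as reported, it was 1841, 2044, 12124, 0 and 7665 with quantile normalization, array median scaling, no filter on dim features, healthy horses only and an adjusted p under 0.10. It was 1796 with the dimmer 50% of features left out, 2474 with the running number as a covariate, 2551 with sets as a fixed block and 888 with pairs as a random block. For endurance against standardbred, 42 as reported, it was 171 with quantile normalization, 130 with array median scaling, 8 with no filter, 162 with the dimmer 50% left out, 899 with array weights, 75 with a trended robust variance prior, 0 with only the arrays compared, 85 with the additive model, 0 with healthy horses only, 274 at an adjusted p under 0.10, 6 with sets as a fixed block, 0 with pairs as a random block and 2 without both raised-floor arrays. The other settings stayed within 1.5 times.

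Leaving out 1 horse gave 380 to 5111 features for standardbred against thoroughbred. It gave 1544, 380, 828 and 3840 without thoroughbred healthy replicates 1, 2, 3 and 4, 5111, 426, 1541 and 534 without thoroughbred inflamed replicates 1, 2, 3 and 4, 689, 4710 and 950 without standardbred healthy replicates 1, 3 and 4, and 949, 1508 and 588 without standardbred inflamed replicates 1, 3 and 4. For endurance against thoroughbred the range was 2019 to 5864, with 2160 and 2943 without thoroughbred healthy replicates 2 and 3, 2391 without thoroughbred inflamed replicate 2, 2324 and 2019 without endurance healthy replicates 2 and 4 and 2857 without endurance inflamed replicate 3. For endurance against standardbred it was 0 to 223, with 1, 11 and 21 without endurance healthy replicates 1, 2 and 3, 0, 2, 8 and 223 without endurance inflamed replicates 1, 2, 3 and 4, 5 and 1 without standardbred healthy replicates 3 and 4, 11, 0, 6 and 10 without standardbred inflamed replicates 1, 2, 3 and 4, 11 and 10 without thoroughbred healthy replicates 2 and 3, and 12 each without thoroughbred inflamed replicates 2, 3 and 4.

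The correlations of inflammation effects did not pass in any setting run. That of thoroughbreds and endurance horses, -0.011 as reported, changed sign with the dimmer 50% left out (0.128) and without both raised-floor arrays (0.020), and ran from -0.083 to 0.070 without 1 horse. With no filter it was -0.168 and with quantile normalization -0.027. Without 1 horse, that of thoroughbreds and standardbreds ran from -0.00486 (without standardbred healthy replicate 1) to 0.175, and that of standardbreds and endurance horses from -0.290 to -0.169. The last was -0.067 with quantile normalization, -0.104 without both raised-floor arrays and -0.157 with the dimmer 50% left out. The named features kept their direction. With no background flags, dim features stay the least certain.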

Other observations

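The tests of the 9 features in this part were chosen after their values were seen. Some features were high in part of the horses and low in the rest, whatever the group. A gap of more than 2 on the log2 scale with at least 4 horses on each side was found for 111 of the 43803 features, against 21.9 on average in normal noise with each feature's own SD, and 34 of the gaps exceeded 4. The features fell into 48 distinct divisions of the horses, of which 14 were shared by at least 2 features. None of the 48 passed for airway inflammation (lowest adjusted p = 0.939, Fisher's exact test), though 2 had an unadjusted p under 0.05. Feature 14087 was high in 12 healthy and 7 inflamed horses (Fisher's exact p = 0.0373). Feature 38958 was high in 9 healthy and 3 inflamed horses (Fisher's exact p = 0.0391). A division with only 4 or 5 horses on a side cannot by itself give a p low enough to pass, so the test says little about such divisions. The division shared by most features, 22 with gaps of 2.00 to 2.39, was the 8 arrays numbered 7006 to 7009 and 7018 to 7021 against the rest, which are 2 whole array sets with 4 thoroughbreds and 4 endurance horses.

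The next division was shared by 9 features, among them 16600, 32883 and 25399, which were high in 7 of 8 endurance horses, 1 of 8 standardbreds and 0 of 8 thoroughbreds, 4 of them healthy and 4 inflamed. The exceptions were endurance healthy replicate 3, which was low, and standardbred healthy replicate 2, which was high. Array sets or scaling were argued against as the source, since the smallest gap was 4.60 where the 75th percentiles of the arrays spanned 1.57, and the division cut through 4 of the 6 sets. It was the 1 division of 48 that went with discipline (Fisher-Freeman-Halton exact p = 0.000526, adjusted p = 0.0253), so a difference in the genetic background of the horses, which discipline carries here, is a candidate explanation. Sex is another, and it cannot be told apart from discipline: 0 features had the opposite division, as an array without male-specific features would also give, and the labels used here do not give sex.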
